A study of Homo sapiens and Mus musculus with 10 samples.

How the data were processed

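RNA was extracted with a column kit and made into stranded poly(A) libraries, per the labels' protocols, which describe the starting material as cultured keratinocytes for all samples although the labels name A375 cells and mouse skin. The authors deposited 1 table of TPM per species, with 63140 human and 78298 mouse gene rows. The builds GRCh38 and GRCm39 are named in the submitters' processing notes. The aligner and the quantification tool are not given in the sources used here. TPM divide by transcript length and by the library total, so that a change in a few abundant genes, or a loss of long transcripts, moves the values of other genes. TPM keep no depth, and no precision from counts can be given.

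Samples were grouped by their labels. The human groups were A375 cells without and with LL-37 (n = 3 each, biological triplicates per the series text). For the mouse libraries (n = 2 each), title and genotype contradict the description of the table column, and groups were named by column. Nothing in the labels says whether the mouse libraries came from separate animals, so that p-values measure the spread between these samples. Human identifiers were named with a gene name table that matched 62541 of them. The mouse table was used with its identifiers.

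Values were analysed as log2(TPM + 1). Genes with at least 1 TPM in at least 3 human or 2 mouse libraries were tested with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, two-sided), and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. Of the fixed lists, 31 were human, and those with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over lists. The 36 mouse lists were not analysed here. Design, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took CAMP, the 10 largest rises and falls among genes past the threshold with at least 5 TPM in the higher group and no overlap, or the 5 largest each way where none passed, and the 2 most abundant members of a described list where none passed. Genes whose list count was small were named after their values were seen. The values of 1 gene that the rule takes are not reported here.

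Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, a replicate block, each library left out, no intensity trend, an absolute log2 change of at least 1, an estimated correlation and TPM without mitochondrially encoded genes. Alternatives chosen after seeing the data were removal of each library's length trend, array quality weights, and LL-37 replicate 3 left out together with length trend removal or an estimated correlation. Transcript length, GC content and coordinates came from GENCODE 29, with the longest transcript per gene, for 13878 of the tested human genes (96.4%). The tests were checked on simulated data with 200 changed genes and each gene's own spread. The changed genes were drawn from the more abundant ones, so recovery of changes in low genes was not tested. Genes were drawn independently, without the deviation that many genes share in LL-37 replicate 3. The rates are therefore not the power or false-call rate for the real libraries. With the spread of all A375 libraries, 33% of 2-fold and 72% of 4-fold changes were recovered in a test over 14399 genes, with 7 false calls among 112. With the spread without LL-37 replicate 3, 91% and 100% were recovered, with 9 false calls among 200. For the mouse comparison, 36% and 74% were recovered in a test over 14537 genes, with 7 false calls among 117.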

Results

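The series held 10 RNA-seq libraries in 2 experiments. In the first, A375 cells, an established human melanoma line, were cultured without peptide (Ctrl, n = 3) or with LL-37 at 80 µg/mL for 24 h (n = 3). LL-37 is the antimicrobial peptide cut from cathelicidin, the product of CAMP. In the second, dorsal skin of mice that had received B16-F0-Luc melanoma cells on day 1 was treated daily with 30 mg imiquimod cream, an agonist of Toll-like receptor 7, from day 15 to day 21 and harvested on day 25. It compared mice with floxed Camp alleles with and without K14Cre, a keratinocyte recombinase (n = 2 per group). Expression was given as TPM, transcript abundances scaled by length and library, which sum to the same total in each library, so that sequencing depth is unknown and no counting interval can be given. Levels below are mean TPM ± SD over the libraries of a group. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes.

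The first comparison asked how A375 cells respond to LL-37. Among gene lists fixed before the data were examined, NF-kB cytokines and regulators, ATF4 stress genes, G2/M cell cycle genes and cholesterol synthesis genes were higher relative to all other genes with LL-37. Genes of the invasive melanoma state and of hypoxia and glycolysis were lower. These calls used camera's preset correlation, and none of them held with an estimated correlation (adjusted p = 0.202 to 0.945). The cholesterol and hypoxia calls also ended without LL-37 replicate 1. Cytosolic ribosomal proteins and nuclear-encoded oxidative phosphorylation genes were also higher, but these 2 calls turned or ended without LL-37 replicate 3. No single gene passed the threshold among the 14399 tested (limma, smallest adjusted p = 0.197), while 363 had an unadjusted p under 0.05 and no gene passed at an absolute log2 fold change of at least 1. In all, 8 of 28 testable lists passed with the preset correlation of 0.01, and none of the 8 passed with an estimated one (smallest adjusted p = 0.202).

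Of the 22 NF-kB genes listed, 16 were measured, and their median log2 change lay 0.46 above the median of all genes (camera, adjusted p = 7.82e-17; adjusted p = 0.202 with an estimated correlation). None passed over all genes tested, and 4 passed adjusted over the list alone, which does not correct for the number of lists. These 4 were the neutrophil chemokine genes CXCL1, CXCL2 and CXCL3 and the interleukin gene IL1A. CXCL1 was 13.1 ± 0.359 TPM in Ctrl and 20.2 ± 0.777 with LL-37. CXCL2 was 2.36 ± 0.317 and 4.71 ± 0.892 TPM, CXCL3 was 3.96 ± 0.316 and 6.97 ± 0.0781 TPM, and IL1A was 20.9 ± 0.81 and 29.98 ± 1.48 TPM. The 2 members with the highest levels were ICAM1, an adhesion molecule gene, at 66.5 ± 4.005 and 59.05 ± 24.8 TPM, and NFKB2, at 48.4 ± 4.52 and 61.3 ± 21.1 TPM. Their log2 changes were -0.27 and 0.27 with all libraries and 0.14 and 0.59 without LL-37 replicate 3. Adjusted over the list alone, 12 passed without LL-37 replicate 3, all higher and with these 4 among them, and 0 passed when any one of the other 5 libraries was left out. The groups did not overlap for 7 of the 16, all higher with LL-37. Over all tested genes this held for 12.4%, where chance gives 10%. The NF-kB list was not alone in a higher share. The groups were apart for 11 of 20 invasive melanoma genes (all lower) and 5 of 10 melanocyte genes (1 higher, 4 lower). They were also apart for 9 of 24 G2/M genes (all higher), 7 of 20 hypoxia genes (all lower) and 7 of 21 ATF4 genes (6 higher, 1 lower). For S phase genes this held for 1 of 24.

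Genes of the ATF4 stress response, which supply amino acids and limit translation under stress, had a median 0.35 above that of all genes (21 of 22 measured, camera, adjusted p = 1.89e-09; adjusted p = 0.432 with an estimated correlation). SLC3A2 was 401.5 ± 14.1 TPM in Ctrl and 403.0 ± 106.4 with LL-37, and SHMT2 was 232.5 ± 1.28 and 259.0 ± 36.7 TPM. Their log2 changes went from -0.03 and 0.15 to 0.21 and 0.26 without LL-37 replicate 3. G2/M genes, which carry cells into mitosis, had a median 0.31 above that of all genes (24 of 24 measured, camera, adjusted p = 6.03e-12; adjusted p = 0.202 with an estimated correlation). This median was 0.20 without LL-37 replicate 3. CCNB1 was 17.5 ± 1.92 and 22.97 ± 3.46 TPM, and UBE2C was 14.7 ± 2.21 and 23.8 ± 1.08 TPM. The cholesterol list had a median 0.10 above that of all genes (23 of 24 measured, camera, adjusted p = 0.0116; adjusted p = 0.909 with an estimated correlation). Its own median log2 change was -0.10 and its mean -0.07, opposite in sign to the test, which compares it with other genes. FDPS was 188 ± 8.38 and 194.2 ± 13.7 TPM, and FDFT1 was 161.5 ± 4.46 and 175.95 ± 20.1 TPM, with log2 changes of 0.05 and 0.12 that were -0.01 and 0.03 without LL-37 replicate 3. The cholesterol call ended without LL-37 replicate 1 (adjusted p = 0.149), with quantile normalization (0.168) and with no filter (0.168). With all libraries, no member of these 3 lists passed over all genes or adjusted over the list alone. Without LL-37 replicate 3, 17 ATF4 members (16 higher, 1 lower) and 4 G2/M members, all higher, passed adjusted over the list alone, and 0 passed when any other library was left out.

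The invasive melanoma list, of genes high in dedifferentiated melanoma cells, had a median log2 change -0.24 relative to all genes (20 of 24 measured, camera, adjusted p = 0.00129; adjusted p = 0.945 with an estimated correlation). This median was -0.13 without LL-37 replicate 3. Its 2 most abundant members were SERPINE2, at 4622 ± 204.1 TPM in Ctrl and 3580.5 ± 1034 with LL-37, and VIM, at 2277 ± 116.4 and 1847 ± 540.8 TPM. Their log2 changes were -0.41 and -0.35 with all libraries and -0.15 and -0.08 without LL-37 replicate 3. With all libraries no member passed over all genes or adjusted over the list alone. Without LL-37 replicate 3, 6 passed adjusted over the list alone (5 lower, 1 higher), with FN1 past the threshold over all genes as well, and 0 passed when any other library was left out. The hypoxia and glycolysis list had a median -0.10 relative to all genes (20 of 22 measured, camera, adjusted p = 0.000619; adjusted p = 0.909 with an estimated correlation), and its call ended without LL-37 replicate 1 (adjusted p = 0.0818). The median was -0.17 without LL-37 replicate 2. None passed over all genes and 2 passed adjusted over the list alone. These were CA9, a carbonic anhydrase gene, at 93.03 ± 20.01 and 39.1 ± 14.5 TPM, and ALDOC, an aldolase gene, at 109.7 ± 10.96 and 68.2 ± 9.38 TPM. Both also passed in this way without Ctrl replicate 1 or LL-37 replicate 2, and were among 7 that passed without LL-37 replicate 3, all lower. None passed without Ctrl replicate 2, Ctrl replicate 3 or LL-37 replicate 1. ALDOA was 1358 ± 108.6 and 1144 ± 137.9 TPM, and LDHA was 496.1 ± 17.5 and 429.5 ± 8.82 TPM. The log2 change of ALDOA was -0.25 with all libraries and -0.15 without LL-37 replicate 3.

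Cytosolic ribosomal protein genes had a median 0.29 above that of all genes (30 of 30 measured, camera, adjusted p = 1.07e-09; adjusted p = 0.432 with an estimated correlation). Without LL-37 replicate 3 the direction turned and the call ended (adjusted p = 0.370). The median was 0.49 without LL-37 replicate 1 and 0.44 without LL-37 replicate 2. RPS18 was 9113 ± 518.9 and 10562 ± 3521 TPM, a log2 change of 0.17 that was -0.09 without LL-37 replicate 3. Nuclear-encoded oxidative phosphorylation genes had a median 0.24 above that of all genes (29 of 29 measured, camera, adjusted p = 0.000548; adjusted p = 0.432 with an estimated correlation). Without LL-37 replicate 3 the list as a whole was lower relative to all genes (adjusted p = 0.0390; adjusted p = 0.535 with an estimated correlation), with no member past the threshold, and that call ended with length trends removed as well (adjusted p = 0.0522). The median was 0.39 without LL-37 replicate 1. COX4I1 was 876.3 ± 18.0 and 893.1 ± 118.3 TPM, and COX7C was 887.3 ± 9.48 and 816.5 ± 23.1 TPM. The log2 change of COX4I1 was 0.02 with all libraries and -0.09 without LL-37 replicate 3. No member of either list passed over all genes or adjusted over the list alone, and both calls ended with quantile normalization (adjusted p = 0.842 and 0.338). The oxidative phosphorylation call also ended with no filter (adjusted p = 0.0520).

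The other 20 testable lists did not pass, with a smallest adjusted p of 0.0831. Measured members numbered 19 for interferon-stimulated genes, 15 for MHC class I presentation, 19 for endoplasmic reticulum chaperones, 12 for cytosolic heat shock, 21 for ERK pathway output, 16 for YAP/TEAD targets and 20 for p53 targets. They numbered 24 for S phase, 15 for the BCL2 family, 10 for melanocyte differentiation, 18 for NRF2 targets, 22 for lysosome, 16 for autophagy, 19 for exosome release and 15 for microRNA processing. There were 6 for LL-37 receptors, 11 for replication-dependent histones and 13 for mitochondrially encoded genes. None of these members passed over all genes, and MT-ND6 alone passed adjusted over the list alone. MT-ND6 did not pass in this way when any one library other than LL-37 replicate 3 was left out. With that library left out, members passed adjusted over the list alone in 17 of the 31 lists, against 3 with all libraries. Among the lists that did not pass, these were 11 mitochondrially encoded genes (10 higher, 1 lower), 4 melanocyte genes (2 higher, 2 lower), 2 ERK genes, both higher, and 2 YAP/TEAD genes (1 higher, 1 lower). There was also 1 member each of the interferon, lysosome and metallothionein lists, all lower, and of the autophagy and exosome lists, both higher. Metallothioneins had 2 measured members and were not tested as a list. Among markers of other cell types, keratinocyte and fibroblast lists had 3 measured members each, leukocyte 2 and endothelial 1, and none passed with all libraries. For 2 of the 3 keratinocyte markers the groups did not overlap, both lower with LL-37. Adjusted over the list alone, KRT10 (adjusted p = 0.00398) and LYZ (0.0236) were lower and KDR (0.0252) higher in limma without LL-37 replicate 3. KRT10 was 25.6 ± 0.534 and 21.1 ± 3.18 TPM, and DSC3 was 2.24 ± 0.0929 and 1.54 ± 0.542 TPM. PDGFRB was 4.04 ± 0.289 and 2.92 ± 1.86 TPM, and PDGFRA was 1.26 ± 0.508 and 1.23 ± 0.186 TPM. CD68 was 36.3 ± 3.82 and 32.1 ± 10.7 TPM, LYZ was 1.95 ± 0.119 and 1.59 ± 0.813 TPM, and KDR was 1.66 ± 0.173 and 1.97 ± 1.05 TPM. Without LL-37 replicate 3 the log2 change went from -0.38 to -0.19 for DSC3, -0.50 to -0.04 for PDGFRB, -0.22 to 0.08 for CD68, -0.23 to -0.47 for LYZ and 0.09 to 0.42 for KDR.

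CAMP (ENSG00000164047, chromosome 3, 48223347 to 48225491, GRCh38) was 1.88, 1.83 and 2.53 TPM in the Ctrl libraries and 1.41, 1.23 and 1.77 TPM with LL-37. Since no gene passed, the genes with the largest differences and no overlap between groups are given as values. MT-ND6, a complex I subunit gene of the mitochondrial genome (positions 14149 to 14673), was 26.8 ± 4.75 TPM in Ctrl and 112.5 ± 49.3 with LL-37, a log2 change of 1.92 ± 0.38 (SE). LCN2, the gene of the iron-binding protein lipocalin 2 (chromosome 9, 128149071 to 128153455), was 3.17 ± 0.686 and 6.69 ± 0.836 TPM. FDCSP was 4.79 ± 0.949 and 9.21 ± 2.11 TPM. A2M, a protease inhibitor gene (chromosome 12, 9067664 to 9116229), was 46.2 ± 4.53 and 15.7 ± 6.64 TPM, a log2 change of -1.60 ± 0.33 (SE). FN1, the fibronectin gene (chromosome 2, 215360440 to 215436172), was 39.5 ± 3.80 and 16.1 ± 7.50 TPM. The adjusted p of each of these was 0.739 (limma, all libraries). With all libraries the log2 change was 0.89 for LCN2, 0.81 for FDCSP and -1.36 for FN1. Without LL-37 replicate 3 it was 2.36 for MT-ND6, 0.98 for LCN2, 0.96 for FDCSP, -1.21 for A2M and -0.91 for FN1. The other 5 were the pseudogenes CYCSP6, RPS27P3 and IPO5P1 and the noncoding TUBA1B-AS1 and DUSP5-DT, whose reads may be shared with copies or overlapping genes.

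**Figure D1:**
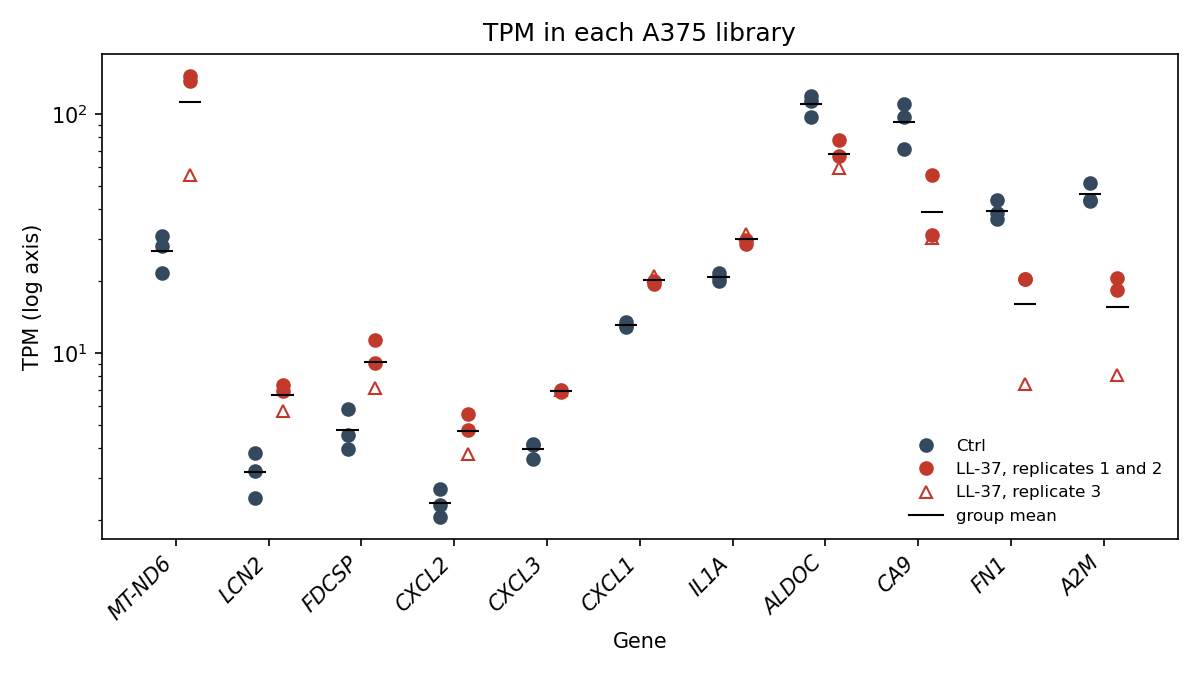
TPM (log axis) of 11 genes in each A375 library, with Ctrl in dark blue and LL-37 in red; open triangles are LL-37 replicate 3 and bars are group means. MT-ND6 averaged 26.8 TPM in Ctrl and 112.5 with LL-37, and A2M averaged 46.2 and 15.7.

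LL-37 replicate 3 stood apart from the other 5 A375 libraries. Its correlation with them over tested genes was 0.949 to 0.963, against 0.985 to 0.992 among the others, and the first principal component, with 76.4% of the variance, separated it. It had 12991 genes at 1 TPM or more, against 14304 to 14555, and its 50 most abundant genes took 39.8% of TPM, against 29.8% to 31.1%. The median log2 change of all genes was -0.20 with this library and 0.00 without it. Leaving it out, an alternative fixed before the data were examined, 17 genes passed, 7 higher and 10 lower, and 1298 had an unadjusted p under 0.05. Leaving out any other library gave 0. Higher were MT-ND6, ELOVL6 (fatty acid elongation), NR4A1, IGFBP3, IL24, C3 (complement) and the noncoding ENSG00000276984. Lower were A2M, FN1, ID1, ID3, CFI, SPARC, SPP1, STC1, VAT1L and the pseudogene RPS28P7. These names were chosen after their values were seen. In LL-37 replicate 3 itself, ELOVL6 (8.64 TPM), NR4A1 (20.8 TPM) and RPS28P7 (28.9 TPM) lay on the other side of the Ctrl mean.

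**Figure D2:**
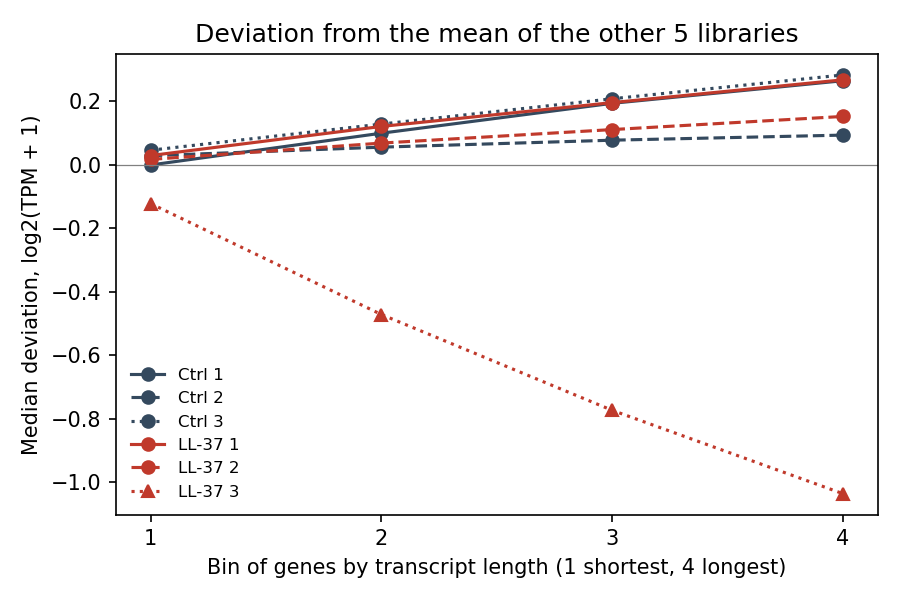
Median deviation of each A375 library from the mean of the other 5, in log2(TPM + 1), over 4 equal bins of genes by transcript length. LL-37 replicate 3 goes from -0.12 in the shortest bin to -1.04 in the longest; the other lines rise in part because replicate 3 is in their comparison mean.

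The second comparison asked how keratinocyte deletion of Camp alters tumour-bearing skin. The labels contradict each other on genotype: libraries titled as knockout are described as the table columns named WT, and the reverse. The groups are therefore named by column, and no direction with respect to genotype is given. Of 14537 genes tested, 9 passed (limma), 3 higher and 6 lower in the columns named cKO, all with an absolute log2 change of at least 1, and 2217 had an unadjusted p under 0.05. Among tested genes whose groups did not overlap, 508 were at least 2-fold higher and 113 at least 2-fold lower in the cKO columns, without regard to the test. Of the 9, 4 had identical values in every library, so that the 9 hold 6 distinct profiles. ENSMUSG00000001131 was 40.9 ± 1.26 TPM in the WT columns and 225.3 ± 15.9 in the cKO columns (n = 2 each), a log2 change of 2.43 ± 0.09 (SE, limma adjusted p = 0.0395). ENSMUSG00000094491 was listed at 0 in both WT columns and at 13.3 and 17.8 TPM in the cKO columns. ENSMUSG00000062353 was 279.2 ± 78.3 and 2.86 ± 0.474 TPM, and ENSMUSG00000057262 was 23.4 ± 3.87 and 0.155 ± 0.219 TPM. The files used here do not pair mouse identifiers with names, so Camp and the mouse gene lists were not analysed here. The groups did not overlap for 51.1% of tested genes, where chance gives 33.3%. The WT columns correlated at 0.980, the cKO columns at 0.956, and libraries of different groups at 0.937 to 0.966. Column cKO replicate 2 correlated at 0.966 with each WT column. Column cKO replicate 1 stood apart on the first principal component (58.55% of the variance), at 53.5 against -36.8 to 3.66 in the others. It had 14970 genes at 1 TPM or more, against 14044 to 14321. How far it drives the 508 and 113 genes was not tested. Without column cKO replicate 2 it is alone in its group. No gene passed without column WT replicate 1, column WT replicate 2 or column cKO replicate 1, and 55 passed without column cKO replicate 2, 47 higher and 8 lower in the cKO columns.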

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

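The length trend and array weight settings, and the settings that join 2 choices, were chosen after the data were seen. The count of 0 genes with LL-37 became 17 without LL-37 replicate 3, 9 with that library left out and length trends removed (all 9 among the 17), and 2690 with array quality weights. The weighting stopped before it converged, with library weights from 0.0316 to 77.5. Leaving out each library gave 0 to 17 genes. An estimated correlation enters only the list test, not the gene test. Every other setting of the gene test gave 0. The count of 8 lists became 0 with an estimated correlation and 0 with LL-37 replicate 3 left out and an estimated correlation, and was 6 to 11 when each library was left out. Median-of-ratios scaling moved the median log2 change of all genes from -0.20 to 0.01. The ribosomal list turned lower without LL-37 replicate 3 (adjusted p = 0.370, range 3.78e-15 to 0.370 over libraries left out), also with length trends removed (0.475) or an estimated correlation (0.827), and its call ended with array weights (0.464). The oxidative phosphorylation list turned lower without it (0.0390, range 3.08e-07 to 0.0390), also with length trends removed (0.0522) or an estimated correlation (0.535), and with array weights (0.513). For the mouse columns, the count of 9 became 3 with a pseudocount of 0.1, 0 with a pseudocount of 5, 0 with no filter, 3 with a filter of 5 TPM and 17 with no trend, and was 0 to 55 when each library was left out; the lone library of an arm is then assumed to vary like the other group. The cause was not tested. With a replicate block, 0 genes (172 at an unadjusted p under 0.05) and 8 lists passed with LL-37. For the mouse columns 6 genes passed with the block, 4 higher and 2 lower in the cKO columns, and 4 of the 6 were among the 9. In the mouse fit 3300 genes had an unadjusted p under 0.05 with the block (limma), against 2217 without it. Same-numbered A375 libraries deviated with correlations of 0.09, -0.20 and -0.17 over genes and the mouse ones with 0.22. These values do not settle whether the numbers pair the samples, and the main tests used no pairing. The mouse settings that need gene names were not run. Depth is unknown.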

Other observations

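The tests of cells of another type, of the mitochondrial share, of the spread left after length removal, of a uniform shift and of the splits for the gene count were chosen after related values were seen. The length test was prompted by short genes seen to be high in LL-37 replicate 3. Without LL-37 replicate 3, the mitochondrially encoded list was higher relative to all genes (camera, adjusted p = 1.52e-13; adjusted p = 0.390 with an estimated correlation). Of its 13 members, 10 were higher and 1, MT-CO3, lower adjusted over the list alone. Endoplasmic reticulum chaperones (adjusted p = 0.000443) and ERK pathway output (0.00213) were also higher and the lysosome list lower (0.000323) in that fit, with adjusted p of 0.535, 0.664 and 0.535 with an estimated correlation. None of these 4 passed with all libraries at the main settings, and each had an adjusted p of 0.945 there with an estimated correlation (camera). With all libraries, the lysosome list passed with quantile normalization (0.00852), no filter (0.0229), length trends removed (0.0479) and array weights (0.00651). The chaperone list passed with median-of-ratios scaling (0.0414), length trends removed (0.0460) and array weights (0.00967), and the mitochondrial list with array weights (2.49e-07).

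LL-37 replicate 3 stood apart. A few genes taking most of the counts would shift all other genes alike, which is argued against by a median deviation -1.17 in the longest relative to the shortest transcripts, against at most 0.151 in size among the others (outside the 50 most abundant genes, mean of at least 10 TPM). Its spread after scaling, 2.13 times the highest of the others, decides nothing here, since 1 factor per library cannot change it. Added keratinocytes, fibroblasts, leukocytes or endothelial cells were argued against by marker sums at most 0.900 times the highest of the others. Cells of any further type were not tested. A stronger form of the response in replicates 1 and 2, as the main source of its spread, was argued against by a correlation of changes over genes of -0.0589. Length trends were not removed for this correlation and can hide a shared response, so that a smaller part stays open. A loss of long transcripts may account for part of it, since its deviation correlated with transcript length at -0.552 (Spearman, across genes, which are not independent), beyond 0.289 among the others, but after length removal its spread stayed 1.83 times the highest of the others. GC content stays open (partial correlation -0.258, with up to 0.411 in size among the others), and no batch is labelled.

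The higher NF-kB list was weighed against the length trend: after its removal the list's median stayed 0.433 above that of all genes, from 0.462, and the list still passed at the preset correlation. With an estimated correlation it did not pass (adjusted p = 0.202, and 0.107 without LL-37 replicate 3). In 10 splits of the 6 libraries, too few for a share under 0.05, the real one gave 8 lists and the others 3 to 7. Thus 1 split, the real one, gave at least 8, but the preset correlation called lists under every split. For single genes the real split gave 0, so that all 10 splits give at least as many by construction and their number says nothing; the highest other gave 3.

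MT-ND6, the gene on the other strand of the mitochondrial genome, was higher in 3 of 3 LL-37 libraries, which the rule for named genes required. A larger mitochondrial share was argued against, since the other genes' median log2 change was at most 0.146 of that of MT-ND6. A general rise of antisense reads across the library was argued against by a median log2 change of 0.0197 in 658 antisense genes without LL-37 replicate 3. Reads opposite the most abundant genes were not tested, since these antisense genes were not sorted by the level of the gene opposite. The 658 went both ways (362 above 0, from -1.22 to 2.11). MT-ND6, at 2.36 in the same fit, was picked for its large rise, so that its place above them decides nothing. RNA from the opposite strand of the mitochondrial genome alone was not tested and could give this pattern.

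ID1, ID2 and ID3, targets of BMP signalling, were 87.1 ± 9.23, 6.71 ± 0.616 and 96.3 ± 5.28 TPM in Ctrl and 48.2 ± 3.90, 3.14 ± 0.462 and 59.9 ± 5.63 with LL-37. With all libraries no gene passed the threshold, these included. Without LL-37 replicate 3, ID1 and ID3 passed over all genes and ID2 did not. Lower BMP signalling was a hypothesis, and 11 other BMP targets had a median log2 change of 0.0217 relative to all genes without LL-37 replicate 3. This median had an SE of 0.0999 over resampled genes, which leaves out the spread between libraries. The median showed no general fall of BMP targets, and the 11 went both ways, from -0.38 to 0.30. It could not exclude a small fall. Their Ctrl means ran from 1.56 TPM (RUNX2) to 16.8 TPM (BAMBI), most of them low, where log2(TPM + 1) understates changes. A fall limited to the ID genes was not tested.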
